A study of Homo sapiens with 4 samples.

How the data were processed

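The series held 4 libraries from DB cells: a ChIP library with an antibody against ZHX2 and an input library for the cells labelled ZHX2, and the same for the cells labelled Mut4. Per the labels' protocols, formaldehyde-fixed chromatin was sonicated, immunoprecipitated overnight, purified and made into Illumina libraries by a service company. The submitters' processing notes name the build hg38 and the tools Trim Galore 0.6.4, FastQC 0.11.9, MultiQC 1.8, BWA 0.7.17, Picard 2.22.2-0, MACS2 2.2.6, HOMER and deepTools 3.4.3, with no role or order. The roles of these tools, the settings of peak calling and the use of the inputs are not given in the sources used here. Libraries were grouped by their titles, which gave 1 ChIP library per arm.

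The analysis used 1 deposited table, the authors' comparison of the 2 ChIP libraries over 8871 peaks. Per the file headers it gives for each peak a log2 fold change and a log2 CPM, made by the authors, with a p-value and an adjusted p-value. It also gives the peak's group (unique to ZHX2, unique to Mut4 or common), position, length, annotation class, distance to the nearest transcription start and gene. The tool that made the table is not given in the sources used here. A positive log2 fold in the deposited table means more signal in ZHX2, since each of the 210 peaks marked as unique to Mut4 is negative. Positions are printed as deposited, and whether starts count from 0 or 1 is not given in the sources used here. Annotation was present in 8827 rows and absent in 44. Input libraries were not used here, and 0 columns of per-sample values were left out.

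Read numbers per library were recovered from the deposited log2 fold and log2 CPM, after the values had been looked at. Each pair of values was solved for 2 whole numbers of reads, with prior counts of 0.25 reads shared between the libraries in the fold and a mean prior of 2 reads and dispersion of 0.05 in the CPM. In 8871 of 8871 peaks (100%) whole reads gave both values back within 1e-09. The library sizes behind the deposited CPM values were the recovered totals over the listed peaks, 541900 and 271694, times factors of 1.04 and 0.965, whose product was 1. Folds are therefore relative to reads in listed peaks, and a difference shared by most peaks is scaled away. The sequencing depth outside the listed peaks is unknown. The ratio of the scaled sizes was 2.14.

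For each peak the scaled fold is the ratio of reads divided by the ratio of scaled sizes. Its exact 95% interval came from the Clopper-Pearson interval of the ZHX2 share of reads. Reads without molecular identifiers are not independent molecules, so intervals cover counting error only. With 0 reads in a library the limit is 3 reads, or 5.34 CPM in ZHX2 and 11.4 CPM in Mut4, and 8 and 17 peaks were at 0 there. Precision was lower in Mut4, with a median of 22 reads per peak against 45.

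The deposited p-values of the authors were checked against an exact negative binomial test of the recovered reads with an assumed dispersion of 0.01. It gave back 99.8% of them within 0.001 on the log10 scale. The counts of peaks under an adjusted p of 0.05 at dispersions of 0.04 and 0.16 used the same test with Benjamini-Hochberg adjustment. With 1 library per arm the spread between cultures cannot be estimated, so no p-value for the conditions was computed.

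The design had foreseen folds or signals without known reads, so no count test was planned, and the intervals were added once whole reads had been found. Peaks were counted by the sign of the deposited log2 fold, annotation class, distance, gene and chromosome, with exact Clopper-Pearson intervals for shares. The named genes follow a rule fixed before the data were examined. It took SLC3A2 and ZHX2, the 8 largest and 8 smallest log2 folds among promoter peaks at or above the median mean signal (1 peak per gene, without symbols that start with LOC, LINC, MIR, SNOR, RNU or RNA5), up to 4 members of each fixed list and the 3 strongest peaks per direction. Of the 8 smallest folds 1 is not reported here. Members of lists without an interval apart from 1 were mostly summarised by count.

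The 17 fixed lists covered ferroptosis defence, ferroptosis drivers, amino acid transporters and mTORC1, ATF4 and the integrated stress response, B cell identity, germinal centre and lymphoma genes, NF-kappaB, antigen presentation, hypoxia, cholesterol synthesis, hepatic genes tied to ZHX2, ZHX and NFY factors, cell cycle, ribosomal proteins, T cell markers, myeloid markers and long neuronal genes. A list's median log2 fold was ranked among 10000 random lists of equal size matched on deciles of mean signal, for lists with at least 3 members. Alternatives were a 4-fold threshold, peaks at or above the median signal, centring on the median, chromosomes 1 to 22 and X, merging within 1000 bp, distances of 1000 and 5000 bp in place of the promoter class, other ways to pick a gene's peak, and matching on peaks per gene. Unscaled reads, scaling to reads at the 104 peaks on unplaced contigs, the 52 of them marked in ZHX2 or the 51 without the strongest of these, other dispersions, leaving out Mut4-only peaks (also past 4-fold) and the interval of each chromosome itself (also over promoters) were added after seeing the data.

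The recovery of reads and the exact test were tried on simulated reads with the real peaks' mean signal and library sizes near the recovered ones. Over 8871 simulated peaks 100% of the reads came back, the exact test called 74.5% of peaks changed 4-fold and 0.127% of unchanged peaks, and 4.47% of unchanged peaks had a raw p under 0.05 by the exact test. The reads were simulated with the same dispersion of 0.01 that the test assumes. These rates therefore do not measure its errors in the real libraries, whose spread is unknown. The ranking of lists was tried on random genes with their real folds. Of 100 such lists without a shift 6% lay outside the central 95%, against 70% of 100 lists shifted by 0.5 in log2. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.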

Results

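Binding of ZHX2, a zinc-finger and homeobox transcription factor, was profiled by chromatin immunoprecipitation and sequencing with an antibody against ZHX2. The cells were DB, an established human diffuse large B-cell lymphoma line. Cells labelled ZHX2 were set against cells labelled Mut4, whose altered residues the labels do not describe. The labels do not say whether the cells also carried endogenous ZHX2, which the antibody would bind in both arms. Each arm had 1 ChIP library and 1 input library. The deposited comparison covered 8871 peaks on hg38 and the 2 ChIP libraries, so no replicate error could be formed and no difference below was tested between conditions. Read numbers, recovered from the deposited fold and mean signal of each peak, summed to 541900 for ZHX2 and 271694 for Mut4 over the listed peaks. The median peak held 45 reads in ZHX2 (quartiles 31 and 67) and 22 in Mut4 (quartiles 14 and 34). Folds given with an interval are scaled ratios of those reads with exact 95% intervals, which cover counting error only.

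The first question was which sites differed between the arms. Of the listed peaks, 8476 (95.5%, exact 95% interval 95.1 to 96.0) were marked as unique to ZHX2, 185 as common to both arms and 210 as unique to Mut4. The ZHX2-only peaks were mostly promoters of genes: 4834 of them, or 57.0% (56.0 to 58.1), carried the promoter class. Among the common peaks 152 of 185 were promoters, 82.2% (75.9 to 87.4), including those of KMT5B, AKT1S1, TPGS1, ARFRP1 and RANBP3. The Mut4-only peaks were of another kind, with 39 promoters among 210 (18.6%, 13.6 to 24.5) and 97 intergenic peaks. By position 52 of the 210 lay on unplaced contigs. Their median length was 187 bp, against 959 bp for ZHX2-only and 1260 bp for common peaks.

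The list of unique peaks and the scaled folds gave different pictures. In the authors' deposited table the median log2 fold of ZHX2-only peaks was 0.027, that of common peaks was -0.32 and that of Mut4-only peaks was -3.12. By sign, 4474 peaks were higher in ZHX2 and 4397 lower, a share of 50.4% higher (49.4 to 51.5). With the recovered reads left unscaled, which moves each log2 fold up by 1.10, the share was 95.9%. Scaled to reads at the 52 peaks on unplaced contigs marked in ZHX2 it was 94.0% (a shift of 0.95), and 82.0% without the strongest of them, on KI270438.1 (a shift of 0.53). Directions given below are relative to the authors' scaling, under which a typical promoter had a fold near 1.

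**Figure D1:**
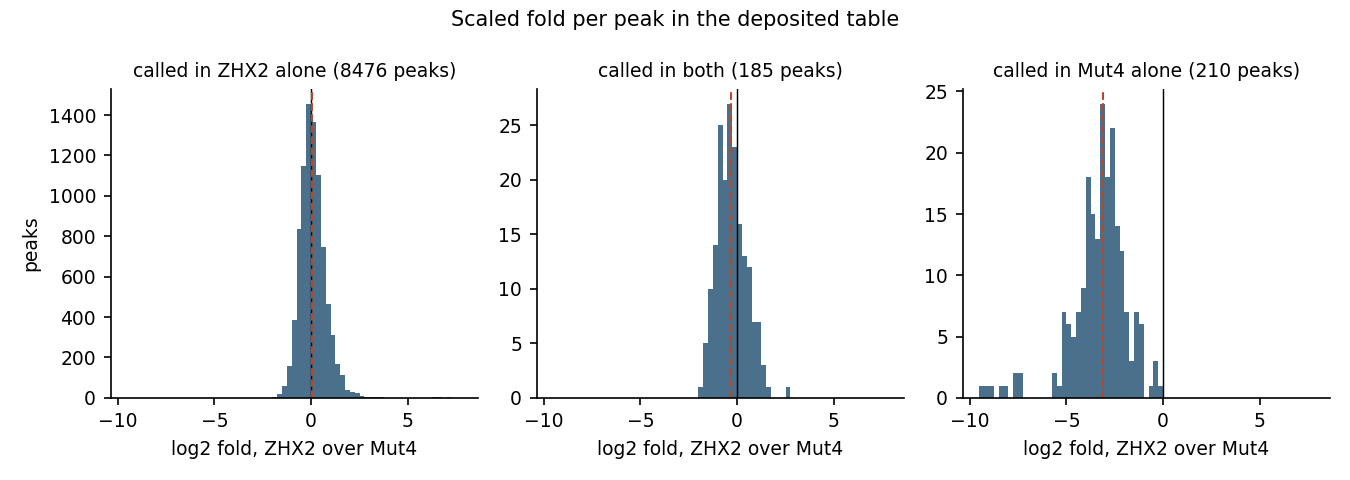
Number of peaks (vertical axes, which differ between panels) by log2 fold of ZHX2 over Mut4 in the authors' deposited table, for peaks marked as unique to ZHX2, common or unique to Mut4. Dashed lines are medians, at 0.027, -0.32 and -3.12; the solid line is 0, and all 210 Mut4-only peaks lie below it.

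Most changes were small under the authors' scaling, with a median absolute log2 fold of 0.41, against 1.13 with unscaled reads. Higher peaks had a median log2 fold of 0.43 (quartiles 0.20 and 0.80) and lower peaks of -0.39 (quartiles -0.66 and -0.19) in the authors' deposited table. Past 2-fold lay 749 higher and 471 lower peaks, and past 4-fold 106 higher and 183 lower peaks. The counting interval of the fold included 1 at 6919 peaks (78.0%). An adjusted p under 0.05 was given by the authors to 528 peaks, 224 higher and 304 lower in ZHX2, and 189 of the lower ones were Mut4-only peaks. Those p-values compare 2 libraries, not the conditions, and follow from an assumed spread: an exact negative binomial test on the recovered reads with dispersion 0.01 gave them back, while dispersion 0.04 left 223 peaks (38 higher, 185 lower) and 0.16 left 30 (7 higher, 23 lower).

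By annotation class and under the authors' scaling, promoters made up nearly equal shares of higher and lower peaks. The shares were 57.4% (2567 of 4474, 55.9 to 58.8) and 55.9% (2458 of 4397, 54.4 to 57.4). This near equality depended on the scaling. With unscaled reads the promoter share of higher peaks exceeded that of lower peaks by 30.1 percentage points. The excess was 22.5 points scaled to the contig peaks marked in ZHX2 and 8.29 without the strongest of these. By distance, again under the authors' scaling, the shares differed. Of higher peaks 78.2% (76.9 to 79.4) lay within 1000 bp of a transcription start, and of lower peaks 69.7% (68.3 to 71.1). Peaks in exons were more frequent among higher peaks, at 12.1% (11.2 to 13.1) against 6.80% (6.07 to 7.58), and intergenic peaks less frequent, at 8.23% (7.44 to 9.07) against 13.2% (12.2 to 14.2). The median distance to a transcription start was 217 bp for higher peaks (quartiles 71 and 703.5 bp) and 241 bp for lower peaks (quartiles 67 and 2225 bp). Among peaks past 4-fold the promoter share of higher peaks exceeded that of lower peaks by 30.6 percentage points, against 1.47 over all peaks, and 182 of those 183 lower peaks were Mut4-only peaks. Peaks were annotated to 7640 genes. Under the authors' scaling 3701 of them had higher peaks alone, 3519 lower peaks alone and 420 peaks of both directions. Over promoter peaks the numbers were 2449, 2358 and 65 of 4872 genes. The even split over all peaks depended on the scaling. Genes with a higher peak numbered 4121 under the authors' scaling and 7424 with unscaled reads. They numbered 7300 scaled to the contig peaks marked in ZHX2 and 6462 without the strongest of these.

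SLC3A2 (ENSG00000168003), the heavy chain of the cystine importer that feeds glutathione synthesis, is the gene in the title of the series. It had 3 peaks on chromosome 11, all marked as unique to ZHX2. The first, a promoter peak at 62856160 to 62857239, held 43 reads in ZHX2 and 42 in Mut4. Its scaled fold was 0.478 (0.305 to 0.750), which is 2.09-fold lower in ZHX2, and the adjusted p in the authors' deposited table was 0.0872. An intronic peak at 62860003 to 62860620 had 38 and 20 reads and a fold of 0.887 (0.503 to 1.61). The other promoter peak, at 62880800 to 62881527, had 50 and 23 reads and a fold of 1.02 (0.608 to 1.74). None of the 3 peaks was higher in ZHX2 beyond counting error under the authors' scaling. With unscaled reads the log2 ratios were 0.034, 0.93 and 1.12. They were -0.12, 0.77 and 0.97 scaled to the 52 contig peaks marked in ZHX2, and -0.54, 0.36 and 0.55 without the strongest of these. The sign at the first 2 peaks therefore depended on the scaling, and the first differed beyond counting error under the authors' scaling alone. With unscaled reads, which keep any difference in depth, the intronic and the other promoter peak were higher in ZHX2 beyond counting error. Scaled to the 52 contig peaks the other promoter peak alone was, and without the strongest of these none was.

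ZHX2 itself (ENSG00000178764) had 1 listed peak, at its own transcription start on chromosome 8, 122780196 to 122783207, marked as unique to ZHX2. It held 482 reads in ZHX2 and 105 in Mut4, a fold of 2.14 (1.73 to 2.67), with an adjusted p of 0.000732 in the authors' deposited table. No other listed peak lay over the gene.

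Among promoter peaks at or above the median signal, those with the largest folds in favour of ZHX2 belonged to genes of several kinds. MORN4 on chromosome 10, 97632843 to 97634251, led with 289 reads against 19, a fold of 7.10 (4.466 to 11.97). KMT5B, a histone H4 lysine methyltransferase, followed on chromosome 11 at 68212732 to 68214485 with 776 against 57 reads, a fold of 6.36 (4.85 to 8.47). Next came the antisense transcript JARID2-AS1 at 4.95 (2.91 to 9.05) and AL118511.1 at 4.90 (2.38 to 11.7). The retinoic acid receptor gene RARA stood at 4.39 (2.57 to 8.05), EBF4 at 4.17 (2.44 to 7.66), the deubiquitinase gene USP7 at 4.05 (2.221 to 8.085) and ENOSF1 at 3.62 (2.77 to 4.79). In the authors' deposited table the adjusted p of these 8 peaks was at most 0.000305, at AL118511.1. The higher peaks of strongest signal lay at the promoters of AKT1S1, a subunit of mTORC1, with a fold of 2.04 (1.74 to 2.40), TPGS1 at 1.57 (1.33 to 1.85) and LINC01134 at 2.503 (2.086 to 3.022).

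In the opposite direction, among the same promoter peaks, that of FZR1, an activator of the anaphase-promoting complex, stood far from all others. Its Mut4-only peak of 490 bp on chromosome 19, 3525871 to 3526361, held 2 reads in ZHX2 and 532 in Mut4, a ratio of 570 in favour of Mut4 (157 to 4716). FP671120.11 and FP236383.9, on the short arm of chromosome 21, were 8.77-fold (7.058 to 10.99) and 5.96-fold (4.06 to 8.93) lower in ZHX2, with the limit that this region is repeated and reads there can be shared between copies. The kinase gene MAP2K7 was 4.96-fold lower (2.96 to 8.60) and ZNF583 3.62-fold lower (2.18 to 6.13). ARFRP1 and RANBP3, common to both arms, were 3.41-fold (2.23 to 5.30) and 3.03-fold (2.00 to 4.64) lower. These 7 peaks held more reads in Mut4 than in ZHX2 before any scaling.

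**Figure D2:**
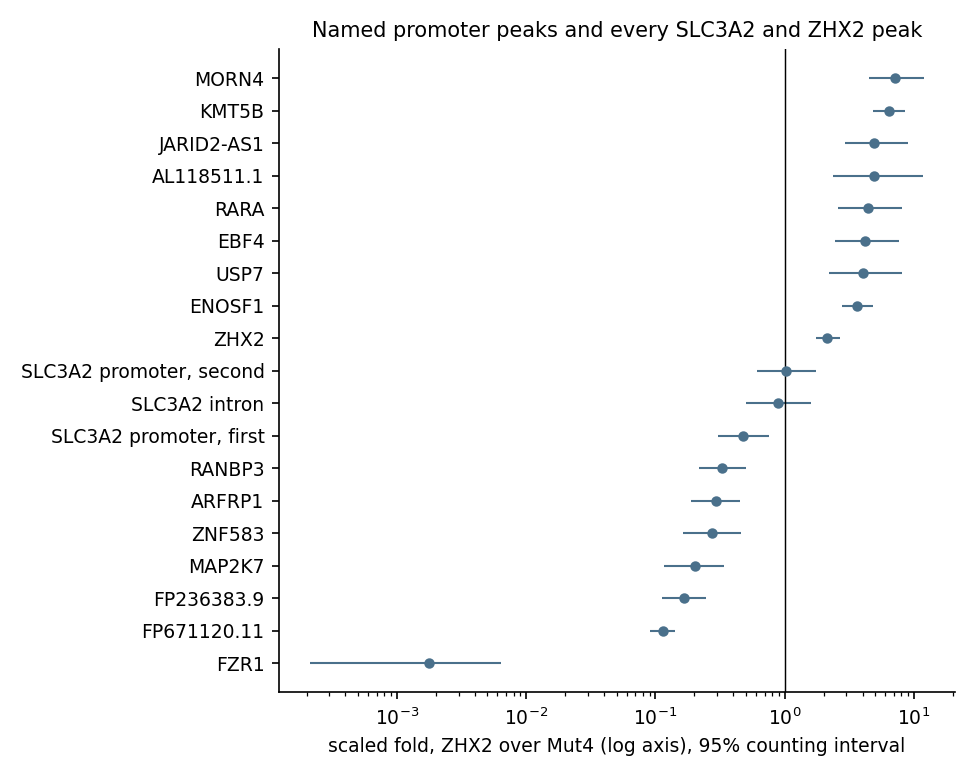
Scaled fold of reads, ZHX2 over Mut4, on a log axis, for the 8 promoter peaks at or above the median signal with the largest fold, 7 of those with the smallest and each SLC3A2 and ZHX2 peak. Points are single ChIP libraries compared, bars are exact 95% counting intervals, and the vertical line is 1; FZR1 lies below 0.00637 and 2 of the 3 SLC3A2 peaks include 1.

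The lower peaks of strongest signal were intergenic or on an unplaced contig. A peak next to the centromere of chromosome 16, 46386414 to 46391364, annotated to the pseudogene ANKRD26P1, held 12079 reads in ZHX2 and 9474 in Mut4, 1.68-fold lower in ZHX2 (1.63 to 1.73). A peak on contig KI270438.1 held 6036 and 6822 reads, 2.42-fold lower (2.34 to 2.51), and another ANKRD26P1 peak had a fold of 0.667 (0.641 to 0.694). The 3 strongest peaks took 4.46% of the listed reads in ZHX2 and 7.56% in Mut4.

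Gene lists fixed before the data were examined were then compared by their peak nearest the transcription start. Of 305 genes on 17 lists, 139 had a peak, which was ZHX2-only at 136 and common at 3. Each list's median log2 fold was placed among 10000 random lists matched on mean signal, as a description of these libraries. Of 15 lists with at least 3 members, 3 lay outside the central 95%, where chance gives 0.75. With unscaled reads each median rises by 1.10 and the percentile stays.

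Ferroptosis genes showed no common shift. Of 25 defence genes 10 had a peak, 3 higher and 7 lower, with a median log2 fold of -0.13 (percentile 25.0). SLC3A2 is on that list and in the title of the series, and the labels do not say how it was chosen, so the list was not taken as independent evidence. TXNRD1, a thioredoxin reductase, had 71 and 64 reads and a fold of 0.518 (0.364 to 0.738), while SCD had 2.10 (0.850 to 6.22). Of 24 driver genes 11 had a peak, 4 higher and 7 lower, with a median of -0.31 (percentile 5.04). That median was 0.024 with the mean over all peaks of a gene, -0.035 over promoter peaks and -0.12 at or above the median signal. Among the drivers ATG5, an autophagy gene, had a fold of 0.419 (0.237 to 0.736), NCOA4, the ferritinophagy receptor, 0.509 (0.274 to 0.953), and KEAP1 1.55 (1.19 to 2.04). No gene of either list had an adjusted p under 0.05 in the authors' deposited table.

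Amino acid transporter and mTORC1 genes split evenly, 7 higher and 7 lower of 14, with a median of 0.011 (percentile 52.1). On this list and that of ferroptosis defence, SLC3A2 counted as higher by its peak 267 bp from a transcription start, with a fold of 1.02. Its promoter peak at 531 bp, with a fold of 0.478, was not the one counted. SLC7A6 had a fold of 1.69 (0.988 to 3.02) and SLC1A5 0.730 (0.481 to 1.12). The ATF4 and integrated stress response list stood higher, with 4 of 7 members above and 3 below, a median of 0.66 and a percentile of 98.8. SHMT2 and ATF4 were its members whose interval excluded 1, at 2.69 (1.26 to 6.59) and 1.69 (1.18 to 2.47). The SHMT2 peak was classed as exon at a distance of -4495 bp from the transcription start, and held 46 and 8 reads. The placing of the list fell within the central range with the mean over all peaks of a gene (median 0.11), at or above the median signal (0.21) and over promoter peaks alone (0.75).

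Germinal centre and lymphoma genes had the clearest shift among lists with over 3 members. Of 15 with a peak 9 were higher and 6 lower, with a median of 0.58 and a percentile of 99.9. TBL1XR1, a corepressor subunit, had a fold of 3.002 (1.344 to 7.890), FOXO1 2.74 (1.54 to 5.22), the plasma cell factor IRF4 2.61 (1.40 to 5.30) and the acetyltransferase gene CREBBP 2.05 (1.11 to 4.08). Of these FOXO1 alone passed in the authors' deposited table, with an adjusted p of 0.0250. Among the 7 members at or above the median signal the median was -0.036 (percentile 50.5). B cell identity genes, 3 higher and 9 lower, lay within the central range with a median of -0.19 (percentile 18.7), and CD37 had a fold of 0.604 (0.378 to 0.975).

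T cell markers, listed as genes of another cell type, had 3 peaks, all higher in ZHX2, with a median of 3.78 (percentile 100). CD28, a T cell costimulatory receptor, had a 585 bp peak, classed at a transcript end, on chromosome 2, 203734782 to 203735367, with 346 reads in ZHX2 and 1 in Mut4, a ratio of 162 (28.8 to 6400). The intronic CD8A peak at 86788460 to 86789415 held 385 and 13 reads, a fold of 13.8 (7.99 to 26.2). The LCK promoter had 62 and 28 reads and a fold of 1.03 (0.652 to 1.68). Of the myeloid markers ELANE alone had a peak, with 21 and 3 reads and a ratio of 3.27 (0.976 to 17.1).

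The remaining lists with at least 3 members lay within the central range. Cholesterol synthesis genes were 6 higher and 6 lower (median -0.022, percentile 48.4), and the mevalonate kinase gene MVK had a fold of 2.30 (1.49 to 3.69) with an adjusted p of 0.0296 in the authors' deposited table. ZHX and NFY factors, 4 higher and 1 lower, had a median of 0.55 (percentile 95.1), with NFYB at 1.985 (1.044 to 4.090). Hypoxia genes were 3 higher and 6 lower (median -0.31, percentile 7.09), but the median of the 4 at or above the median signal was 0.31, again within the central range. KDM3A had a fold of 1.60 (1.15 to 2.25). NF-kappaB genes were 3 higher and 6 lower (median -0.077, percentile 43.7), with RELA at 0.652 (0.433 to 0.988). Cell cycle genes were 1 higher and 8 lower (median -0.17, percentile 20.3), and ribosomal protein genes 4 higher and 10 lower (median -0.19, percentile 13.5). Antigen presentation genes were 2 higher and 1 lower (median 0.11, percentile 39.7), and long neuronal genes 3 higher and 3 lower (median -0.013, percentile 21.7). Of the hepatic genes tied to ZHX2, too few for a placing, H19 and SREBF1 had a peak, with folds of 1.11 (0.464 to 2.93) and 0.934 (0.498 to 1.82).

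The share of higher peaks varied by chromosome. On chromosome X 122 of 166 peaks were higher in ZHX2, 73.5% (66.1 to 80.0), against 50.4% on the other chromosomes, and over X promoters the share was 71.6% (61.0 to 80.7). Over all peaks chromosome 7 had the lowest share, 37.3% (33.5 to 41.2), followed by chromosome 21 at 38.0% (29.6 to 46.9), chromosome 20 at 39.2% (34.1 to 44.4) and chromosome 19 at 39.9% (36.6 to 43.3). Among promoters the lowest shares were 33.8% (22.6 to 46.6) on chromosome 21 and 36.6% (32.2 to 41.1) on chromosome 19, with chromosome 7 at 42.1% (36.4 to 47.9). Of 23 chromosomes, 12 lay above and 6 below the exact interval of all others. That interval leaves out the counting error of the chromosome itself, so a share can lie outside it by counting error alone. By each chromosome's own interval 8 lay above and 5 below, and over promoter peaks 3 lay above (3, 4 and X) and 4 below (7, 11, 19 and 21). Below the others' interval lay 7, 11, 18, 19, 20 and 21, and above it lay 1, 2, 3, 4, 5, 6, 9, 12, 13, 15, 22 and X. Of these, chromosomes 5, 12, 13, 18 and 22 held the share of the others within their own interval.

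**Figure D3:**
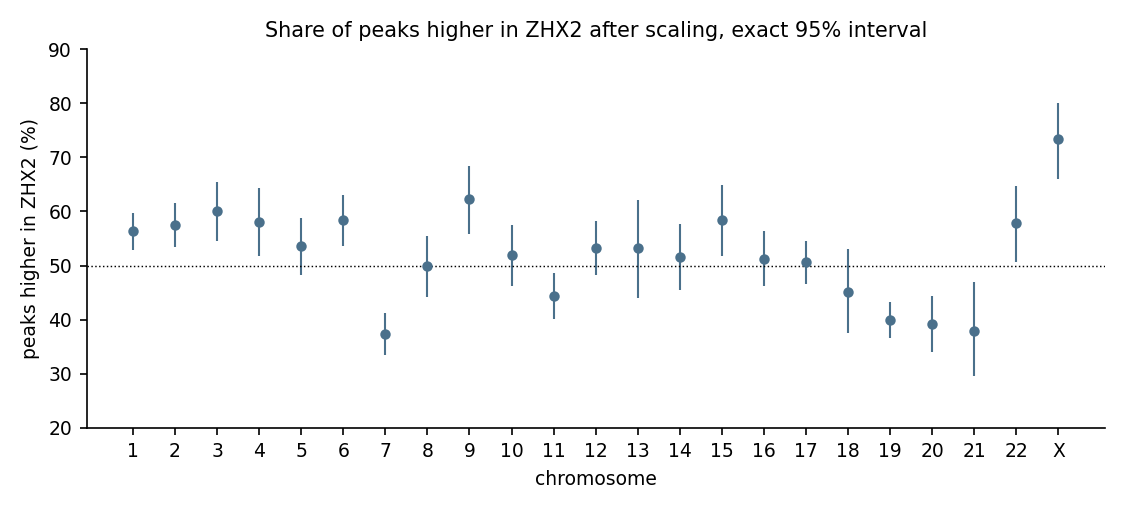
Percentage of listed peaks higher in ZHX2 than in Mut4 after the authors' scaling (vertical axis) on chromosomes 1 to 22 and X. Points are shares of peaks, bars are exact 95% intervals of counting error, and the dotted line is at 50%; chromosome X lies at 73.5% and chromosome 7 at 37.3%.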

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

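Settings without scaling, scaled to unplaced contigs, with other dispersions, without Mut4-only peaks or with a chromosome's own interval were chosen after seeing the data, the others before the data were examined. The contig references were the 52 peaks marked in ZHX2, the 51 without the strongest, and all 104, of which 52 were Mut4-only peaks, so that the last reference was selected for reads in Mut4 and its shifts follow in part from that. The references of 52 and 51 peaks were in turn selected for reads in ZHX2, which acts on their shifts in the opposite direction. The share of higher peaks stayed within its counting interval after centring on the median, on chromosomes 1 to 22 and X and after merging, and was 36.7% past 4-fold, 45.4% at or above the median signal, 95.9% without scaling, 94.0%, 82.0% and 97.4% scaled to the 52, 51 or 104 contig peaks, 51.7% without Mut4-only peaks and 99.1% past 4-fold without them. The promoter share of higher minus lower peaks, 1.47 points, was 30.6 past 4-fold, 30.1 without scaling, 22.5, 8.29 and 41.3 scaled to the 52, 51 or 104 contig peaks, 41.5 past 4-fold without Mut4-only peaks (where 1 lower peak was left), 8.43 for distances within 1000 bp and 6.75 within 5000 bp. It stayed within its counting error, but with the opposite sign, at or above the median signal (-0.522) and without Mut4-only peaks (-0.398), and was 0.416 on chromosomes 1 to 22 and X and 0.946 after merging. Genes with a higher peak, 4121, numbered 92 past 4-fold, 1951 at or above the median signal, 7424 without scaling and 7300, 6462 and 7514 scaled to the 52, 51 or 104 contig peaks, of which the lower counts follow from fewer peaks. The median absolute log2 fold, 0.41, was 0.38 at or above the median signal and 1.13 without scaling. The median distance to a transcription start, 24 bp longer for lower peaks, was 13058 bp longer past 4-fold. Chromosomes outside the interval of the others, 18, were 21 over promoters, 13 by their own interval and 7 over promoters by their own interval. At the first SLC3A2 peak, with 43 and 42 reads, the log2 ratio of -1.06 was 0.034 without scaling, a changed sign, -0.12 and -0.54 scaled to the 52 or 51 contig peaks and 0.36, also of changed sign, to all 104. In each of these other settings its counting interval included 0. The second, at -0.17 with an interval that included 0, also changed sign, to 0.93 without scaling and 0.77, 0.36 and 1.25 scaled to the 52, 51 or 104, and the last, at 0.022, kept it, at 1.12, 0.97, 0.55 and 1.45. The ZHX2 peak, at 1.10, went to 2.199 without scaling and 2.045, 1.63 and 2.52. Peaks under an adjusted p of 0.05, 528, were 223 and 30 at dispersions of 0.04 and 0.16 and 339 without Mut4-only peaks, by the exact test of 2 libraries. Of 55 list settings 51 kept their side of the central range. The integrated stress response list left it at 0.21 at or above the median signal, 0.11 with the mean over a gene's peaks and 0.75 over promoters. The sign of the median changed for the germinal centre list (-0.036) and the hypoxia list (0.31) at or above the median signal, for ferroptosis drivers with the mean over a gene's peaks (0.024), and for amino acid transporters with that mean (-0.0023) and over promoters (-0.00049). Past 4-fold no list of the 15 had 3 members, and 5 more combinations had too few, so these gave no value. Except for the shifts that scaling sets by construction, the cause was not tested. No paired analysis was possible because each arm had 1 ChIP library. At a median of 22 Mut4 reads per peak, 78.0% of peaks had a counting interval that included a fold of 1.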

Other observations

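All tests in this part, and the gene families named, were chosen only after the results had been seen. Replication-dependent histone genes, which the fixed lists had not covered, stood higher in ZHX2. Of 28 with a peak 22 were higher and 6 lower, with a median log2 fold of 0.74, against a central range of -0.26 to 0.25 for random lists matched on signal. H4C12 on chromosome 6, 27830641 to 27831857, had 54 reads in ZHX2 and 4 in Mut4, a fold of 6.30 (2.32 to 24.0). H2BC4 stood at 3.002 (1.700 to 5.711) and H2AC15 at 2.80 (1.58 to 5.34), while H2AC20 had 0.709 (0.494 to 1.03). Over the 13 genes with a promoter peak the median was 0.82. Most of these genes sit in clusters on chromosome 6 and are not independent.

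Among 57 families of at least 10 genes that share the letters of their symbol, 5 lay outside the central 95%, where chance gives 2.85. The variant U1 RNA genes (RNVU, 10 genes) had a median of 0.92, the LRRC genes 0.52 and the DENND genes 0.50. On the lower side the RPL family, which includes pseudogenes, had a median of -0.31 over 39 genes, while the 34 ribosomal protein genes of both subunits alone had -0.23, within the central range (-0.25 to 0.20), and -0.19 at promoters. The 211 zinc-finger genes named ZNF had a median of -0.15, with 74 higher and 137 lower. The random lists were not matched on chromosome. A shift of a family therefore cannot be told apart here from a shift of the chromosomes that hold its members.

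Over 23 chromosomes, with Mut4-only peaks left out, the median folds of promoter and other peaks had r = 0.585 (permutation p = 0.00345) and rho = 0.465 (permutation p = 0.0256). Without chromosome X alone r was 0.413 (permutation p = 0.0557) and rho 0.389 (permutation p = 0.0726). Without chromosomes X and 19, picked as the 2 farthest, r was 0.380 (permutation p = 0.0854) and rho 0.326 (permutation p = 0.144).

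The 8476 peaks marked as unique to ZHX2 had a median scaled log2 fold of 0.027. The authors' scaling may account for this, since the recovered totals and sizes gave a product of scaling factors of 1, so the sizes were reads in listed peaks and a difference common to most peaks was scaled away. Without selection of peaks, a difference in sequencing depth alone predicts 1 read ratio everywhere. Among peaks marked in ZHX2 the ratio of ZHX2 to Mut4 reads was 2.203 (2.16 to 2.24, resampled peaks) at promoters. On unplaced contigs it was 1.112 (0.9579 to 1.8005), or 1.48 (1.25 to 1.958) without the strongest contig peak. Both sets were selected for reads in ZHX2, which can act unequally on weak and strong peaks. The gap therefore does not exclude depth alone. Weaker enrichment in the Mut4 library, whether from a less efficient precipitation or from less binding of the mutant protein, stays open and cannot be told apart here, because the inputs were not used, each arm had 1 library and the labels do not say whether endogenous ZHX2 was present.

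Chromosome X peaks were higher in ZHX2 than autosomal peaks by 0.34 in log2 (0.21 to 0.46, resampled peaks). Lower signal of X peaks is argued against, since the shift was 0.378 (0.16 to 0.57) at or above the median signal. The shift at promoters, 0.302 (0.17 to 0.38), lay below the 0.58 of 3 copies against 2 and the 1 of 2 copies against 1. Outside promoters it was 0.505 (0.17 to 0.63), below 1 but with an interval that included 0.58. These values argue against 2 copies in place of 1 in all cells only if binding per copy differed alike on chromosome X and the autosomes, which was not tested. They do not decide on 3 against 2, since the interval outside promoters reached it and folds hold binding as well as copy number. A copy number difference in part of the cells, or on more copies, is a candidate explanation that also stays open. Binding of the mutant that differs by chromosome was not tested, nor was GC content.

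The peaks at CD28, CD8A and FZR1 had nearly all their reads in 1 library, with 346 against 1, 385 against 13 and 2 against 532. Other listed peaks were one-sided too. Intergenic peaks on chromosome 17 annotated to AC131274.3 and AC069061.1 held 188 reads in ZHX2 against 2 in Mut4, 114 against 0, 96 against 0 and 89 against 0. They lay between 1749973 and 2119649 bp from the transcription start they were annotated to. In the opposite direction another AC131274.3 peak held 0 against 27, and an AL592188.2 peak on the unplaced contig GL000220.1 held 0 against 50. Whether reads at these other peaks could be shared between repeated copies was not tested. The explanations below were weighed for CD28, CD8A and FZR1 alone. Stray DNA fragments in 1 library could give sites that stand alone, as CD28 and CD8A did with no other listed peak within 50 kb, while FZR1 had 3. Of those neighbours 0 differed at least 4-fold the same way, but an isolated binding site would look alike, so the explanations cannot be told apart. Chromatin of T cells in the ZHX2 library would raise other T cell genes, and LCK, the other marker with a listed peak, had a fold of 1.034 (0.652 to 1.68), which is too few genes to decide. FZR1 is not a T cell marker and differed in the opposite direction.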
